A study of Homo sapiens with 4 samples.

How the data were processed

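Nuclei of cells that the labels call HepG2, a line derived from a human liver tumour, were profiled by snHH-seq, a method that gives each nucleus a barcode built from a well-specific primer and a bead. Per the labels' protocols, cells were treated for 48 h with drug compounds or with complete medium only, nuclei were reverse transcribed in the wells of a 96-well plate with primers that carry a well barcode, and all nuclei were then pooled, tailed and put in droplets with barcoded beads. Per the labels, the 4 samples are 2 libraries, each with a first and a second entry, and all 4 belong to 1 group. The series names 4 drugs and their combinations.

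The authors deposited 1 table of natural log values for 29726 genes in 46901 cells. In each cell the exponential of the deposited value minus 1 summed to 10000, so the values are the natural log of 1 plus the count per 10000 counts. Whole counts were read back from the smallest value of each cell, and 100% of the values came out whole within 0.01. cutadapt, UMI-tools, STAR and Scanpy and the genome build GRCh38 are named in the submitters' processing notes, without versions or roles. The filters on cells, the gene annotation and the strand setting of the counting are not given in the sources used here. In the table, cells held 301 to 4965 counts, at least 95 genes and at most 69.86% mitochondrial counts. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and the counts of gene families with near-identical copies, such as tubulins, histones, ferritins and ribosomal proteins, are uncertain for the single members.

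Each cell name gives its sample and 40 bases, of which the last 10 took 44 values over the whole table. These 10 bases were read as the well barcode. The segments of 10 bases before them took 96, 48 and 48 values, so the first segment has as many values as a 96-well plate has wells. The reading was not checked further, and all results by well rest on it. Nothing used here says which well held which drug, so the planned comparisons of each treatment with medium and of the combinations with their single drugs were not made. Wells were not sorted into treatment groups, and no sets of wells were compared with each other. Ranges over wells and the relation between libraries across wells are given instead.

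The first and second entries of a library shared nearly all cell barcodes (99.27% and 99.66% of the first), while other pairs shared 14 to 31 barcodes. They were taken as repeat runs of the same nuclei, their mean was used as 1 replicate, and n is 2 libraries throughout. Both libraries come from 1 pool of nuclei, so every SD is technical spread. The table held 31672 distinct cells.

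Cells were clustered with Scanpy 1.11.5 and igraph 0.11.9 under Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3). The settings were 2000 variable genes among genes in at least 1% of cells, values limited to 10 SD, 30 principal components, 15 neighbours and Leiden resolution 0.5, with seed 1. No doublet caller was run. As a measure of crowding, 20.13% of droplet barcodes in library 1 and 15.33% in library 2 held more than 1 well barcode. No cluster had more than 1 gene of any cell type marker list among its 10 leading genes, so clusters stay unnamed and carry a number or their leading gene.

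Levels are counts per 1000000 counts (CPM). In a cluster and in the other cells they are the mean over cells of each cell's own CPM, averaged over runs and libraries. Levels of liver genes, of lists summed over all cells of a library and of wells are instead pooled counts over pooled totals. Ratios are log2 of CPM plus 1, which understates changes of low genes. For each of 33 gene lists, fixed before the data were examined, the median log2 ratio of its measured members was placed among 10000 random lists of the same size matched on mean level. A list was taken to stand apart below percentile 2.5 or above 97.5. No p-value was computed from cells. Members count as higher or lower at 1.5-fold, genes of a cluster at 2-fold. Named genes followed a rule fixed at the same time: the 10 genes with the highest ratio per cluster among genes in at least 10% of its cells, and per list up to 4 members with the highest mean level among those changed 1.5-fold. Any other gene named was chosen after its values were seen, as were PDE3A, which names a cluster, and HSPA8. XIST and Y-linked genes are not reported. Shares of cells with a count were compared after thinning each cell to 300 counts, which left out no cell. Gene positions are from GENCODE v29 on GRCh38, which held 71.06% of the gene names by symbol. Intervals are 95% exact (Clopper-Pearson for shares, Poisson for counts) and, like the limit of 3 counts for a count of 0, cover counting error only.

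For wells, lists were summed in second runs, within the PDE3A-high cluster and the other cells separately, scaled to totals without mitochondrial counts. Wells with at least 30 cells of the population in each library were used. Pearson's r and Spearman's rho between libraries were tested by two-sided permutation (100000 resamples, smallest p 1e-05) with Benjamini-Hochberg adjustment at 0.05. A simulation without any well effect first called lists that have few counts. After that, and after the well values had been seen, the test was limited to wells with an expected count of at least 10 in both libraries and to lists with at least 20 such wells. The relations of HSPA8 with the other population and with well properties used levels summed over both libraries, and there the minimum of 10 applied to the sum. With this limit the simulation without effect called 0 of 270 list tests over 10 rounds. When some wells, about as many as not, were raised by 1.5-fold, 96.67% were called. The simulation used totals of the other cells only and counting error alone. It does not cover the PDE3A-high cluster or further spread between cells.

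The comparison of the PDE3A-high cluster with the other cells was tested on simulated data with 2000 genes. Of genes changed by 1.5-fold, 37.31% passed the 1.5-fold bound in the right direction. For 2-fold and 4-fold changes this was 100%, and 0% of unchanged genes passed. Only the more abundant genes were simulated, with counting error as the sole spread. These rates therefore do not cover low genes, such as many of the NF-kB and interferon lists, whose median members were at 1.64 and 1.63 CPM. Of 200 random lists, 5% fell outside the central 95%. This checks the calculation only, since these lists were drawn at random from the same simulated genes. It does not cover real lists, whose genes can vary together.

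Alternatives were other pseudocounts, detection filters, deeper cells, totals without mitochondrial and ribosomal genes, other cluster resolutions and variable genes, and each replicate left out. The alternatives for wells, for clusters without list members or without the 1% minimum, and for differently matched random lists were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.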

Results

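The data were 46901 expression profiles of 31672 distinct nuclei, from 1 pool of cells labelled HepG2 and exposed to drugs or medium for 48 h, in 2 libraries that each appear in 2 runs. The series asks how cells within a drug screen differ in their response. The first runs (replicates 1 and 2) held 6683 and 8624 cells with 3585350 and 4799043 counts, and the second runs (replicates 3 and 4) held 17350 and 14244 cells with 14357722 and 9202383 counts. The median cell had 446, 452, 647 and 510 counts in replicates 1 to 4, and 228, 237, 315 and 261 genes. A count of 0 allows a level of up to 0.837, 0.625, 0.209 and 0.326 CPM in these samples.

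Mitochondrially encoded transcripts made up 48.7% of all counts, and the ribosomal RNAs MT-RNR2 and MT-RNR1 alone took 18.3% and 9.79%. The nuclear long noncoding RNAs NEAT1, a scaffold of paraspeckles, and MALAT1 took 0.348% and 0.116%. Ribosomal protein transcripts took 0.454%. Albumin (ALB), the main plasma protein made by hepatocytes, had 1 count among 23560105 in the second runs (0.0424 CPM, 95% interval 0.00108 to 0.237). Alpha-fetoprotein (AFP) had 0 counts (upper 95% limit 0.157 CPM) and apolipoprotein B (APOB) 3 counts (0.127 CPM). The hepatocyte regulators HNF4A and FOXA2 were at 1.10 and 0.0424 CPM. Other genes linked to liver or liver cancer were well above these levels: GPC3, a cell-surface proteoglycan, at 84.8 CPM, ONECUT2 at 77.3, the imprinted RNA H19 at 58.0, RXRA at 39.5 and complement C3 at 37.3 CPM. Of the 14 measured secreted hepatocyte proteins 13 were under 1 CPM, and their sum was 40.6 ± 2.91 CPM (SD, n = 2 libraries). For scale, the median gene with a count was at 1.36 CPM.

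**Figure D1:**
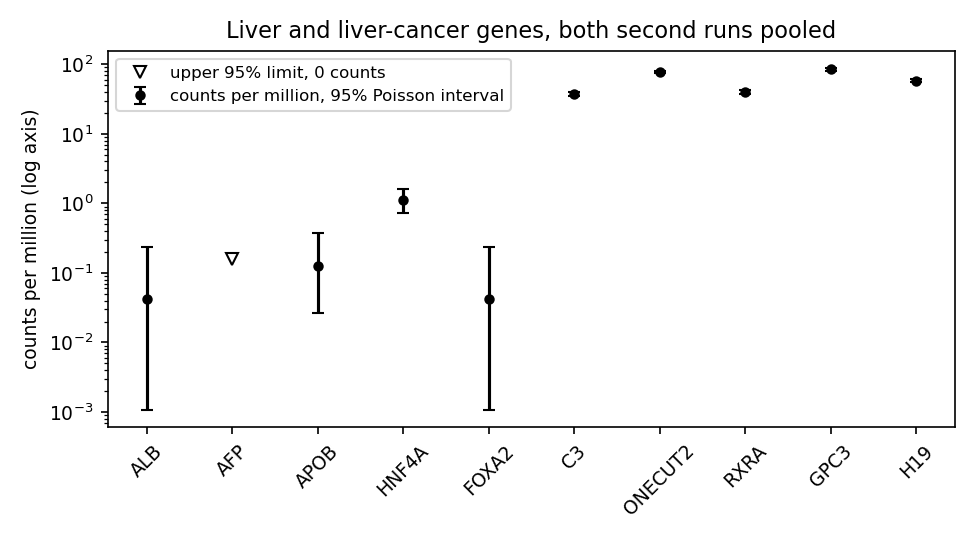
Levels of 10 genes in CPM (log axis) over both second runs pooled, with 95% Poisson intervals as bars and an open triangle for the upper limit of a gene with 0 counts. ALB lies at 0.0424 CPM and GPC3 at 84.8 CPM.

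The first comparison asked how alike the samples of the pool were. Mean log2 profiles over 29726 genes correlated between samples with r from 0.9909 to 0.9965, and over the 1680 genes in at least 5% of cells from 0.9948 to 0.9974. These correlations run across genes, which are not independent replicates. Among these 1680 genes, leaving aside XIST and Y-linked genes, 0 differed by more than 1.5-fold between libraries in both runs (no test). Over all genes, which include many of few counts, 255 differed by more than 2-fold between replicates 1 and 2. Between replicates 3 and 4 this was 5 genes. Summed levels of cell cycle lists were close in both libraries, with S phase genes at 1778 ± 14.6 CPM and G2/M genes at 1291 ± 4.26 CPM (SD, n = 2). Leukocyte markers summed to 0.879 ± 0.109 CPM and endothelial markers to 11.02 ± 0.706 CPM. Second runs of library 1 gave 2.54 counts and of library 2 gave 1.48 counts per first-run count of the median shared cell.

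The second comparison asked which populations of cells the pool held. Clustering gave 3 clusters. Cluster 3 held 26.5% ± 0.844 of cells (SD, n = 2 libraries) and was marked by PDE3A, a phosphodiesterase that breaks down cyclic nucleotides, at 2606 CPM against 67.97 CPM in other cells. It was 27.8% of cells in replicate 1 (95% interval 26.7 to 28.9), 28.3% in replicate 2, 24.1% in replicate 3 and 25.9% in replicate 4 (25.2 to 26.7). Thinned to 300 counts, 49.4% of its cells and 1.93% of the other cells had a PDE3A count (70.0% and 4.12% unthinned, median depths 558 and 517). AMOT, which encodes angiomotin, ran the other way, with a count in 2.85% of thinned cells of the cluster and 28.1% of the others (6.89% and 46.3% unthinned). In cells seen in both runs the call as PDE3A-high was the same in 99.35% and 99.31%, against 59.95% and 59.48% by chance.

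**Figure D2:**
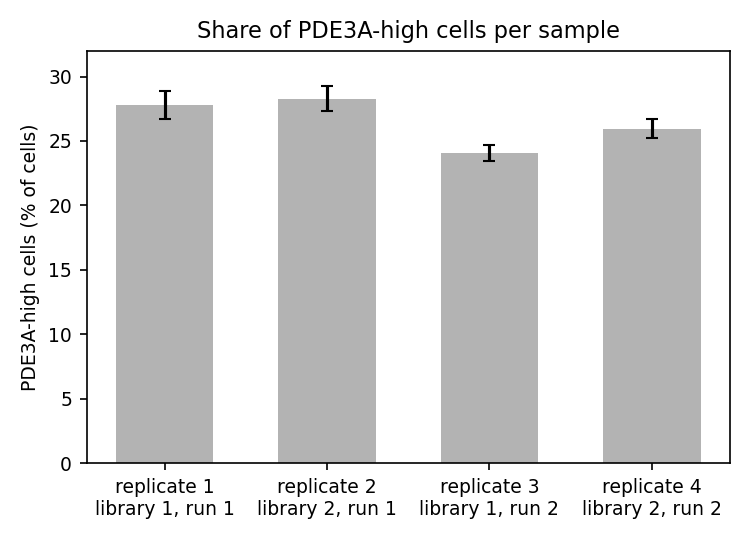
Share of PDE3A-high cells, in percent of cells, in each of the 4 samples, with exact 95% binomial intervals as bars. The shares run from 24.1% in replicate 3 to 28.3% in replicate 2.

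The genes that lead the PDE3A-high cluster describe it and are not a test, since clusters were made from the same genes. The 10 leaders were CCAT1, KYNU, C5orf17, MIR100HG, GDA, PIEZO2, WISP2, MYPN, H19 and KRT7. KYNU, an enzyme of tryptophan breakdown (chromosome 2, 142877498 to 143055832), stood at 585.6 against 7.79 CPM, a log2 ratio of 6.08 ± 0.06 (SD, n = 2). MIR100HG, the host RNA of a microRNA cluster (chromosome 11, 122028327 to 122556721), had a log2 ratio of 5.83 ± 0.26. KRT7, a simple-epithelium keratin (chromosome 12, 52232520 to 52252186), had 5.60 ± 0.02 and H19 (chromosome 11, 1995176 to 2001470) 5.66 ± 0.10. Of the 507 genes with a count in at least 10% of this cluster's cells, 182 were at least 2-fold higher than in other cells. This filter favours genes that are high in the cluster.

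Clusters 1 and 2 held 38.9% ± 1.40 and 34.6% ± 0.557 of cells. In replicates 1 to 4 cluster 1 held 31.63%, 35.04%, 48.19% and 40.82% and cluster 2 held 40.6%, 36.69%, 27.76% and 33.24%, so the repeat runs differed by far more than these SDs between libraries. Cluster 1 was led by CACNB4, a calcium channel subunit (226.9 against 80.03 CPM), MAGI2, CREB5, ZNF536, ZNF704, DTNA, FMN2, PRKG1, DAB1 and MDGA2, and 49 of 791 genes were at least 2-fold higher. Cluster 2 was led by AMOT (1115 against 759.1 CPM), RPS4X, PTMA, DLEU1, ST6GALNAC3, FHIT, PLCB1, MT-ND3, AUTS2 and GPC6, and 0 of 150 genes reached 2-fold. Median depth was 694 counts in cluster 1 and 402 in cluster 2, with mitochondrial shares of 43.8% and 52.1%. Cells seen in both runs stayed in the same one of these clusters in 48.0% (library 1) and 70.5% (library 2), against 44.3% and 49.5% by chance, so that only the PDE3A-high cluster is compared further.

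The third comparison set the fixed gene lists in the PDE3A-high cluster against the other cells. Of 33 lists 17 stood apart from random lists, 16 above and 1 below, where chance would give 1.65. Some lists share members, such as FTH1 and FTL in the NRF2 and ferroptosis lists and TNFRSF10B in the p53 and apoptosis lists. The 17 are therefore not independent results. The medians of the random lists were themselves centred below 0, at -0.49 to -0.06 depending on the list, so that a list can lie above them without being raised. This applies to apoptosis regulators (median 0.08), heat shock (0.10), secreted hepatocyte proteins (0.13), fatty acid oxidation (0.14) and autophagy (0.15). Of 32 lists with a value, 14 did so against protein-coding genes matched on level and gene length, all 14 among the 17. With members in at least 5% of cells only, 8 of 17 lists with a value stood apart. The lists of NRF2 targets and of ferroptosis and iron genes were among those above. Ferritin heavy chain FTH1 was at 1012 against 167.5 CPM (log2 ratio 2.59 ± 0.07, SD, n = 2 libraries) and light chain FTL at 125.4 against 40.09 CPM (1.62 ± 0.07). TXNRD1, thioredoxin reductase, had a log2 ratio of 2.44 ± 0.07 and TKT, of the pentose phosphate pathway, 1.32 ± 0.03. Of 17 NRF2 targets 9 were higher and 0 lower (median 0.77 ± 0.07, percentile 100). In the ferroptosis and iron list TFRC, the transferrin receptor, had 2.34 ± 0.02 and SLC7A11, the cystine transporter, 0.77 ± 0.10. Of its 15 genes 5 were higher and 4 lower (median 0.26 ± 0.47, percentile 99.3), and the SD of this median exceeds its size.

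The lists of ERK pathway output, NF-kB and interferon genes also had medians above 0 in the PDE3A-high cluster. Of 17 genes of ERK pathway output 10 were higher and 2 lower (median 1.02 ± 0.06, percentile 100). The receptor kinases went apart, with EPHA2 at 3.13 ± 0.06 and EPHA4 at -3.70 ± 0.37. The immediate early factor EGR1 had 1.29 ± 0.19 and MYC 0.67 ± 0.23. Of 13 NF-kB genes 7 were higher and 0 lower (median 0.73 ± 0.15, percentile 100), with the adhesion receptor ICAM1 at 3.12 ± 0.36 and BIRC3 at 2.19 ± 0.14. NFKBIA had 0.97 ± 0.14 and TNFAIP3 0.88 ± 0.17. Of 15 interferon genes 9 were higher and 2 lower (median 0.82 ± 0.13, percentile 99.99), among them OAS3 at 4.06 ± 0.28 and IFI6 at 2.18 ± 0.30, with ISG15 at -1.32 ± 0.15 and IFI27 at -1.50 ± 0.63. These lists hold many genes of few counts, with summed levels of 89.6 CPM for NF-kB and 137.7 CPM for interferon genes in the cluster.

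WNT targets were the list that lay below. Of 14 genes 9 were lower and 2 higher (median -1.77 ± 0.11, percentile 0.01). NKD1, a feedback inhibitor of the pathway, had -3.60 ± 0.33, the stem cell receptor LGR5 -3.40 ± 0.03, glutamine synthetase GLUL -2.23 ± 0.02 and the transcription factor LEF1 -1.56 ± 0.11. The oncofetal gene GPC3 stood at 5.74 against 116.6 CPM (-4.20 ± 0.34) and MDK at -2.09 ± 0.15, while H19 and PEG10 (4.59 ± 0.17) were higher. That fetal liver list had 4 of 11 genes higher and 6 lower, and its median of -0.70 ± 0.13 was at percentile 10.2. This median depends on which members enter: it was 4.59 (percentile 99.99) with members in at least 5% of cells only, and its percentile was 1.54 with a pseudocount of 0.1 and 70.8 without replicate 1. Of the hepatocyte transcription factors NR5A2 had -1.70 ± 0.36, PROX1 -1.88 ± 0.44, ONECUT2 -0.67 ± 0.08 and RXRA 0.94 ± 0.05 (percentile 82.4).

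Among stress and survival lists, 11 of 22 p53 targets were higher and 3 lower (median 0.55 ± 0.12, percentile 99.99). The most abundant of the members changed 1.5-fold went both ways: SESN2 -1.76 ± 0.04, CCNG1 -0.94 ± 0.55, the death receptor TNFRSF10B 0.88 ± 0.27 and CMBL 1.25 ± 0.17. Of 19 apoptosis regulators 6 were higher and 3 lower (median 0.08 ± 0.01, percentile 99.0), with BCL2L1 at 1.51 ± 0.01, XIAP at -0.96 ± 0.06 and HRK at -2.60 ± 0.14. Of 16 autophagy and lysosome genes 7 were higher and 1 lower (0.15 ± 0.02, percentile 99.1), with the cargo receptor SQSTM1 at 1.31 ± 0.09, ULK1 at 1.67 ± 0.16 and LAMP2 at -0.94 ± 0.14. Hypoxia and glycolysis genes had a median of 0.18 ± 0.00 (8 of 22 higher, 4 lower, percentile 99.8, but 92.3 with members in at least 5% of cells), with NDRG1 at 1.65 ± 0.01, P4HA1 at 1.00 ± 0.07 and PFKFB3 at -1.25 ± 0.07. Heat shock genes had a median of 0.10 ± 0.01 (percentile 98.0), a call lost with random lists matched on the mean of both populations (96.3), with protein-coding genes matched on level and length (95.8), without replicate 1 (95.04) and with members in at least 5% of cells (65.9, median -0.23). Named members were HSPD1, a mitochondrial chaperone, at -1.01 ± 0.08, HSPB1 at 0.80 ± 0.16 and HSPA1A at 3.09 ± 0.59 (9.40 against 0.195 CPM). Tubulin genes had 0.26 ± 0.14 (percentile 99.0, but 96.6 with members in at least 5% of cells), with TUBA1C at 0.83 ± 0.14 and TUBA1A at -0.93 ± 0.03.

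The remaining lists that stood apart also lost this under at least 1 alternative. They were mitochondrially encoded genes (median 0.45 ± 0.01, percentile 99.6, lowest 96.7), nuclear long noncoding RNAs (0.24 ± 0.37, percentile 97.6, lowest 94.6), PI3K and FOXO targets (0.30 ± 0.10, percentile 99.3, lowest 95.5), fatty acid oxidation (0.14 ± 0.11, percentile 98.1, lowest 93.0) and secreted hepatocyte proteins (0.13 ± 0.01, 2 of 12 higher, percentile 99.45, lowest 94.2). In these, NEAT1 had 2.05 ± 0.03, MALAT1 2.82 ± 0.06, KCNQ1OT1 -4.18 ± 0.28, IRS2 2.01 ± 0.42, CPT1A 1.09 ± 0.08 and C3 4.94 ± 0.13. The median mitochondrial share of counts was 54.6% in the PDE3A-high cluster. Leaving mitochondrial and ribosomal genes out of the totals moved the median gene by 0.19 on the log2 scale.

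Lists within the random range included DNA repair (15 of 20 lower, 1 higher, median -0.83 ± 0.03, percentile 3.55, but 1.60 against random lists matched on the mean of both populations), with the repair sensor PARP1 at -1.49 ± 0.01 and BLM helicase at -1.15 ± 0.04. S phase genes had a median of -0.47 ± 0.06 (percentile 39.2), with DTL at -0.92 ± 0.15, and G2/M genes -0.12 ± 0.13 (percentile 96.0), which turned to 0.04 with mitochondrial and ribosomal genes left out of the totals and to 0.30 (percentile 98.0) with members in at least 5% of cells. The integrated stress and unfolded protein list had -0.53 ± 0.12 (percentile 37.9), with the serine synthesis enzymes PSAT1 at -1.68 ± 0.11 and PHGDH at -1.70 ± 0.11. Cytosolic ribosomal proteins had -0.53 ± 0.00 (percentile 29.5), with RPS4X at -1.81 ± 0.17. Cholesterol biosynthesis (-0.32 ± 0.11), fatty acid synthesis (-0.30 ± 0.05), xenobiotic metabolism (0.04 ± 0.09), TGF-beta genes (-0.10 ± 0.10) and histones (-0.47 ± 0.47) were at percentiles 73.6, 73.8, 96.5, 92.4 and 43.1. Xenobiotic metabolism passed the bound with a pseudocount of 0.1 (98.2), in deeper cells (99.94), with random lists matched on the mean of both populations (97.7) and without replicate 2 (98.3). The TGF-beta median turned to 0.09 with those genes left out of the totals. Markers of other cell types were at percentile 74.2 (fibroblast), 49.8 (leukocyte), 14.9 (endothelial) and 88.2 (cholangiocyte, 98.1 without replicate 1), and single members stood out, with COL1A1 at 2.44 ± 0.01, CDH5 at 4.30 ± 0.06 and SOX9 at -2.38 ± 0.09.

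**Figure D3:**
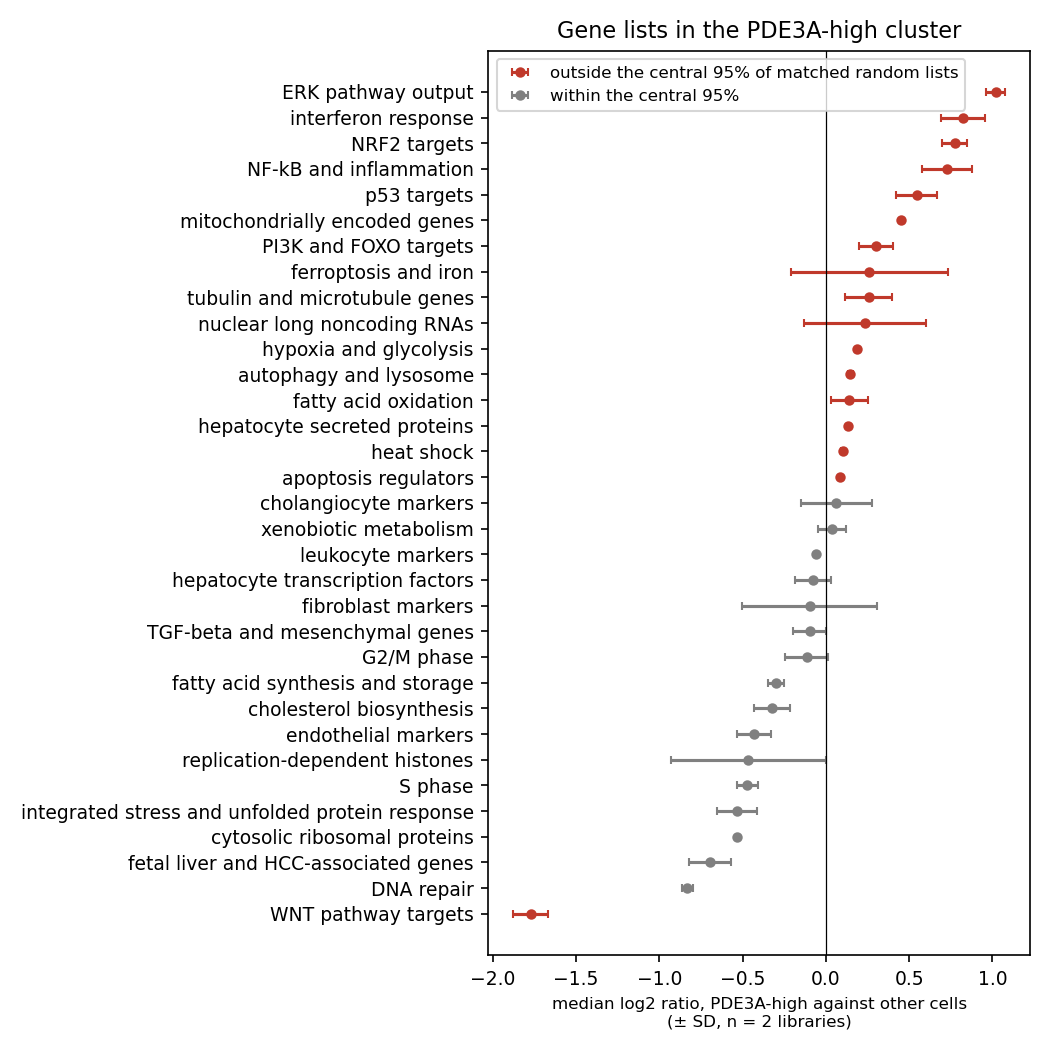
Median log2 ratio of the members of each of 33 gene lists, PDE3A-high cluster against other cells, as points with the SD over 2 libraries as bars. Red points mark the 17 lists outside the central 95% of matched random lists, from WNT targets at -1.77 to ERK pathway output at 1.02.

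Which gene programs the drugs or their combinations changed could not be compared, because no source used here ties the well barcodes to treatments. A limit for the lists above is that both populations were pooled over wells, and so over treatments. Wells did not enter them equally, since the share of PDE3A-high cells ran from 13.7% to 44.3% over 44 wells in second runs. List levels within a population also differed between wells, so small list ratios cannot be told from a different mix of wells. With 2 libraries of 1 pool the SDs measure technical spread.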

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

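Among the tests below, the bounds for depth, for gene names, for lowering by treatment and for response to treatment were chosen only after the results were seen. Of 41 values per sample (depth measures, cluster shares and summed list levels), 1 had a sample far from the others. Replication-dependent histones were at 155.4 CPM in replicate 1 against 139.4 and 136.5 CPM at the ends of the others so that the gap to the nearest was 0.847 of the whole range, above Dixon's 95% critical value for 4 samples. That value, and the 2.05 such cases (about 1 in 20) it gives by chance, assume independent samples, whereas these are repeat runs of 2 libraries, so the gap is a description and not a test. No biological explanation was tested for it.

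Liver genes lay near the floor in a line described as liver. Too little depth is argued against by the upper limit for albumin, 0.237 CPM, since 9034 genes exceeded 10 CPM. Wrong gene names are argued against by 14 mitochondrially encoded genes among the 20 most abundant. Lowering by treatment would leave counts of ALB, AFP and APOB in wells with medium only, but no well barcode held more than 1 count of the 3 genes together in the second runs, and 40 of 44 wells held none. This test needs each well barcode to mark 1 treatment and medium-only wells to be among the 44. Neither was shown here, so it does not decide. The identity of the cells stays open and was not tested against any reference.

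The pool held 2 separated populations. A response to treatment alone would leave wells with medium only almost without PDE3A-high cells, yet the lowest share in any well was 13.7% (51 cells, lower 95% bound 5.70%). This does not exclude that treatment shifts the share. Mitochondrial or ribosomal transcripts as the cause are argued against by 98.8% of PDE3A-high cells staying together when clustered without these genes.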

How the results depend on the processing

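The settings for wells, and those with clusters made without list members, without a minimum on variable genes or with other random lists, were chosen only after results were seen. The share of PDE3A-high cells stayed between 26.4% and 26.6% under the other cluster settings, except 23.9% in deeper cells, and was 25.63% to 27.52% with each replicate left out. Resolution 1.0 gave 6 clusters. Genes at least 2-fold higher numbered 9 in cluster 1 and 36 in the PDE3A-high cluster when only genes in at least 25% of a cluster were tested, which offers fewer genes, and 347 in cluster 1 by the share of cells with a count. The lists that stood apart numbered 14 to 19, except 8 of 17 with members in at least 5% of cells only, and 11 lists did so in every other setting: p53, NRF2, hypoxia, ERK, WNT, NF-kB, interferon, apoptosis, ferroptosis, autophagy and tubulin. These 11 are not independent, since some share members. Of the medians of lists that stood apart, heat shock turned to -0.23 with members in at least 5% of cells and fatty acid oxidation to -0.00376 without replicate 3 (-0.00376 to 0.2509 with each replicate left out); the cause was not tested. Other medians turned too: with those members fetal liver genes to 4.59, G2/M to 0.30 and TGF-beta to 0.27, without mitochondrial and ribosomal genes in the totals G2/M to 0.04, TGF-beta to 0.09 and fibroblast markers to 0.06, in deeper cells TGF-beta to 0.02, and with a replicate left out TGF-beta to 0.02, fibroblast markers to 0.20, cholangiocyte markers to -0.14 and xenobiotic genes to -0.02. The lowest correlation of samples was 0.9948 over genes in at least 5% of cells. Over all genes it was 0.9909, and 0.9909 to 0.9936 with a replicate left out. Lists following the well numbered 9 (other cells) and 7 (PDE3A-high) in first runs, where p53, heat shock, hypoxia, cholesterol, fatty acid synthesis, WNT, TGF-beta and ferroptosis lists in other cells and G2/M and integrated stress lists in PDE3A-high cells lost the call, and in PDE3A-high cells 5 in cells of 300 to 600 counts, 5 without the most abundant member and 20 with all genes in the total. NRF2 and autophagy lists in other cells were called in first runs (0.504 and 0.615) and not in second runs. ERK output in other cells turned to -0.0337 in cells of 300 to 600 counts, and TGF-beta genes to -0.0738 in first runs. The alternatives planned for treatments and combinations were not run, since wells are not tied to drugs. A count of 0 in a replicate allows up to 0.777 to 2.79 CPM in PDE3A-high cells and 0.286 to 1.20 CPM in the other cells, so lower levels cannot be told from 0.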

Other observations

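In this part, the tests of the mix of populations and of well depth, the added control and intervals named below, and all analyses of wells were chosen only after results were seen. Summed levels of some gene lists followed the well barcode in both libraries. Well properties did so too: the mitochondrial share of counts (39.16% to 65.05%) with r = 0.9905 and the log2 number of cells with r = 0.9581. These were tested together with the share of PDE3A-high cells below. Median depth ran from 385.5 to 1232 counts. Both libraries share the reverse transcription of a well, so their agreement cannot tell its treatment from its handling, depth or quality. Wells hold unknown treatments, so ranges are given and no sets of wells are compared with each other. In the other cells 18 of 26 lists tested, and in the PDE3A-high cluster 12 of 23, had a positive correlation between libraries across wells at an adjusted permutation p under 0.05. In first runs, which hold fewer counts, 9 and 7 lists did so, 7 of each being among those of the second runs. In PDE3A-high cells 5 lists did so in cells of 300 to 600 counts, 5 without the member with most counts and 20 with all genes in the scaling total. In every setting that gave them a value 8 of the 18 lists kept this in other cells (S phase, G2/M, cytosolic ribosomal proteins, integrated stress, tubulin, nuclear long noncoding RNAs, fetal liver genes and histones) and 5 of the 12 in PDE3A-high cells (NRF2 targets, tubulin, nuclear long noncoding RNAs, fetal liver genes and heat shock). Fetal liver genes, histones and heat shock had no value in at least 1 setting. Heat shock genes ranged from 832.1 to 3142 CPM (median 1225) over 38 wells in the other cells, with r = 0.93 (permutation p = 1e-05, the smallest possible, adjusted 3.5e-05; rho = 0.90; r = 0.90 without the 2 outermost wells). In first runs this was lost (r = 0.38, adjusted permutation p = 0.0781, rho = 0.17). In the PDE3A-high cluster they ranged from 630.7 to 3072 CPM over 37 wells (r = 0.77, permutation p = 1e-05). Cytosolic ribosomal proteins ranged from 2706 to 8390 CPM in the other cells (r = 0.90), led by RPS2 from 186.4 to 4550 CPM (r = 0.96). These levels are scaled to totals without mitochondrial genes.

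The ferritin gene FTH1 ranged from 700.1 to 6015 CPM over 39 wells in the PDE3A-high cluster (r = 0.77) and from 121.6 to 684.4 CPM over 29 wells in the other cells (r = 0.67). Cholesterol biosynthesis genes ranged from 791.0 to 1911 CPM in the other cells (r = 0.78, adjusted permutation p = 3.5e-05), but in first runs r was 0.29 (adjusted permutation p = 0.18). In the second runs of the PDE3A-high cluster r was 0.10 (adjusted permutation p = 0.578), or 0.400 (adjusted permutation p = 0.0137) with all genes in the scaling total. The difference between populations was not tested. PSAT1, of serine synthesis, ranged from 90.8 to 629.9 CPM (r = 0.88, 31 wells) and the proliferation marker MKI67 from 238.4 to 744.3 CPM (r = 0.78, 33 wells) in the other cells. MALAT1 ranged from 3248 to 18980 CPM in the PDE3A-high cluster (r = 0.94, 39 wells). Over 44 wells the share of PDE3A-high cells ran from 13.7% to 44.3% (median 24.1%), and the libraries followed each other with r = 0.853 (permutation p = 1e-05, adjusted 1e-05 over 3 measures; rho = 0.80; r = 0.84 without the 2 outermost wells). The widest gap lay between 29.04% and 34.58%. Within the narrower range of the 30 wells below it r was 0.29 (permutation p = 0.114, rho = 0.45, permutation p = 0.0128) and within the 14 above 0.38 (permutation p = 0.18). Depth of the wells was not taken into account. The wells with the highest shares, 44.3% and 43.6%, had median depths of 428 and 470.5 counts. The deepest wells, at 1232 and 1210 counts, had shares of 20.2% and 20.3%. Each of the 14 wells above the gap had a median depth of 532.5 counts or less. The lowest share was also in a well of 428 counts, but that well held only 51 cells. A relation of the share to depth was not tested, so the agreement between libraries cannot be set apart from depth.

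HSPA8, a constitutive chaperone chosen after its values were seen, ranged from 48.4 to 226.4 CPM over the 20 wells of the other cells with an expected count of at least 10 in both libraries (r = 0.60, adjusted permutation p = 0.00986; r = 0.33 without the 2 outermost wells). Over 35 wells that reach this minimum only in both libraries summed, which are used for the relations below, it ranged from 48.4 to 1117 CPM. A different mix of the 2 populations would not make it move in both, but its level in one followed that in the other with r = 0.757 over 29 wells (adjusted permutation p = 0.00014, rho = 0.53), with a bootstrap interval of 0.435 to 0.891, added later, that lies above the bound of 0.3 set for a mix. Without the 2 outermost wells r was 0.593, and over all 39 wells it was 0.565, or 0.4353 without those 2. For base composition of the well primer, the rank correlation of HSPA8 with GC content was -0.0539 (bootstrap interval -0.441 to 0.338, added later), or -0.125 over all 39 wells. These values argue against a strong relation only, since the interval leaves a moderate one possible. Depth of the cells in a well stays open: in cells of 300 to 600 counts r between libraries was 0.297 over 40 wells (rho = 0.4805, adjusted permutation p = 0.0056), which by itself met the bound of 0.3 set for depth as the cause, and HSPA8 fell with well depth (rho = -0.553, adjusted permutation p = 0.00245). A control added after that value was seen, drawing as few counts from all cells, gave 0.211 to 0.704 (median 0.518), so 772 counts are too few to decide, and only 6 of these wells reach the minimum of 10 expected counts.

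A hypothesis is that the pool may hold cells of 2 different lines. Of 10 genes typical of epithelial carcinoma lines, listed before the test, 10 were at least 2-fold higher in the PDE3A-high cluster, such as KRT18 (132.7 against 9.46 CPM), CD44 (108.5 against 4.15 CPM) and AXL (87.0 against 2.69 CPM). Of 10 genes typical of embryonic kidney lines 6 of the 9 measured were at least 2-fold higher in the other cells, below the preset 7, with CKB at 107.5 against 36.1 CPM and DPYSL3 at 47.3 against 2.35 CPM, while NES went the other way (3.22 against 12.6 CPM) and MAP1B differed by 1.40-fold. TUBB2B also belongs to the tubulin list. The test therefore leaves cells of different lines undecided, and states of 1 line stay open as well.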
